A study of Mus musculus with 4 samples.

How the data were processed

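Total RNA from 2 neurosphere samples, 1 wild type and 1 labelled E2f4 knockout, was prepared with RNeasy columns and converted to biotin-labelled cRNA without further amplification, per the labels' protocols. Each RNA was run on the Affymetrix MOE430A and MOE430B arrays, which carry different probe sets apart from 100 in common. The deposited values are MAS5 signal values on a linear scale, with MAS5 named in the submitters' processing notes and no version given in the sources used here. The values themselves show that each array was scaled by the authors to a mean signal of about 1500 after trimming 2% at each end, with no detection calls in the tables used here. Per the file headers of the instrument records, the wild-type and knockout arrays of a design were hybridised on the same day and the designs on 2 different days, so genotype and day were not confounded, and the values within each design are the values within each day.

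Signals were taken to log2, and the log2 ratio of knockout over wild type was computed per probe set within each design and centred on its median, a shift of -0.003 on MOE430A and -0.001 on MOE430B. A probe set counted as measured where both arrays were at or above a floor, the median signal of the design, 735 for MOE430A and 942 for MOE430B. This left 10402 of 22690 probe sets on MOE430A and 9530 of 22575 on MOE430B, and the 64 control probe sets of each design were left out. Where 1 array alone was above the floor, the brighter signal over the floor gave a bound, written as at least N-fold. Gene names came from the platform annotation, looked up through gene identifiers in a RefSeq table of the assembly GRCm38.p6, which changed no symbol; 20380 probe sets of MOE430A and 14661 of MOE430B had 1 symbol, 691 and 245 had several and 1555 and 7605 had none. Of 18193 symbols, 18032 had their identifier in that table. A gene's value was the mean over its measured probe sets on both designs, and probe sets with several symbols or none named no gene. Some genes named below had further probe sets below the floor in 1 or both samples, which did not enter their value. Examples are Mbp, with 1 measured and 7 not, and Laptm5, with 1 and 4. The number of arrays limits the precision, and with 1 sample per genotype no test across samples was possible.

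A set of 29 gene lists was fixed before the data were examined. The median of each list was placed among the medians of 10000 random lists of the same size, matched on 10 groups of mean signal and on 1 against more measured probe sets, and a list was said to stand apart outside the central 95% of these. The percentile describes these arrays and is no p-value. Percentiles under the alternatives, of chromosomes and of simulated lists came from fewer random lists. Lists with fewer than 5 measured genes got values only. Named genes followed a rule fixed before the data were examined. It took E2f4 and the E2F family list, the 10 largest ratios each way among genes with more than 1 measured probe set all at least 2-fold the same way, the 8 largest each way with 1 measured probe set, per list up to 6 members at least 2-fold different or else the 3 largest, and the 5 largest bounds each way, passing over clone names among the single genes and bounds. Other list members are named with a statement that they were chosen after their values were seen.

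The procedure was tested on simulated arrays of all probe sets. Their noise at each signal level was set from the median absolute log2 ratio observed between knockout and wild type. This noise includes any real differences between the samples. In the simulated arrays, 200 genes drawn from the 10174 measured ones differed between knockout and wild type. Of 4-fold genes that stayed above the floor, 33 of 33 higher and 31 of 31 lower were found at the 2-fold size rule; of 2-fold genes, 20 of 48 and 20 of 47 were, with median estimates of 0.98 and -0.96. Of the 10016 unchanged genes above the floor in the simulated arrays, some of which were below it in the real ones, 67 exceeded 2-fold. Of 200 simulated lists of 20 unshifted genes, 9 fell outside the central 95%, and with a shift of 0.3 on the log2 scale 200 of 200 lay above it. The genes of these lists varied independently, so lists whose genes vary together were not tested. Neither were lists of fewer genes.

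The alternatives were a floor at the 30th or 70th percentile, no floor, a pseudocount equal to the floor in place of it, the deposited scaling without centring, quantile normalization, a lowess correction with a span of 0.3, the brightest probe set per gene, leaving out probe sets whose names end in _x_at, _s_at or _a_at, and each design alone. Other choices of list members, chosen after seeing the data, are named as such in the closing section. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.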

Results

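Neurospheres, floating clusters of neural stem and progenitor cells grown in culture, were profiled from the forebrain of mouse embryos at mid-gestation (E12.5). The labels give the ventral telencephalon, the lower part of the embryonic forebrain, as the source for both genotypes. There was 1 RNA sample from wild-type neurospheres and 1 from neurospheres labelled as E2f4 knockout, and each RNA was hybridised to an MOE430A and an MOE430B array, which makes 4 arrays. E2F4 is a transcription factor of the E2F family that, with pocket proteins, represses cell-cycle genes. There were no replicates of either genotype, so no value below carries a p-value or an error across samples, and a difference between the samples was not shown to be a difference between the genotypes. Median signals were 735 and 736 on the MOE430A arrays of wild type and knockout, and 941 and 942 on the MOE430B arrays. The ratio of 3' to 5' Gapdh signal, a sign of RNA integrity, was 0.862 in the wild type and 0.898 in the knockout on MOE430A, and 0.948 and 0.799 on MOE430B.

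The labels state the purpose as finding which signalling pathways E2f4 deletion affects in neural stem cells. Genes of the ventral telencephalon were lower in the knockout sample, with a list median log2 ratio of -0.38 and 13 of 14 measured genes lower; the median was -0.22 without GABAergic and Lhx6 or Lhx8 genes, a choice made after seeing the data. Genes of the dorsal telencephalon, the future cortex, were higher, with a median of 0.36 and 14 of 19 measured genes higher. Genes of neurons in general were lower, with a median of -0.21 and 22 of 26 measured genes lower. The Sonic hedgehog pathway list had a median of 0.21, and its member Gas1, a cell-surface co-receptor for Sonic hedgehog, was 2.42-fold higher in the knockout sample. Shh itself was at -0.34 and the pathway target Ptch1 at -0.04, both chosen after their values were seen. The targets Gli1 and Hhip were below the floor, so the list median was not shown to reflect pathway activity.

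E2f4 itself was represented by 1 probe set, on MOE430A, with a signal of 1812 in the wild type and 1535 in the sample labelled knockout. This was a log2 ratio of -0.24, or 1.18-fold lower. Among 588 genes of like signal and probe set number it stood at percentile 27.6, where the central 95% of ratios ran from -1.08 to 0.86. The position of this probe set relative to the deleted part of the gene is not given in the sources used here, so its signal does not check the genotype label. The other E2F family members and pocket proteins lay close to 0, with a list median of 0.06 and 10 of 17 measured genes higher. The sign of this median held in 8 of 11 alternatives. It was -0.008 with the brightest probe set, -0.08 without _x_at, _s_at and _a_at probe sets and -0.10 on MOE430B alone. E2f1 had a log2 ratio of 0.06, E2f3 of -0.07, E2f5 of 0.04, Rb1 of -0.14 and Rbl1, the gene of the pocket protein p107, of 0.17. Rbl2, the gene of the pocket protein p130, was above the floor in the knockout sample alone, with signals of 714 in the wild type and 750 in the knockout sample, and Lin9 was below it in both. The farthest from 0 were Lin54 at -0.69 and Lin52 at -0.35, both of the DREAM repressor complex, and Mybl2 at 0.50.

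The ventral list was led by Lhx8, a transcription factor of forebrain cholinergic neurons, with a signal of 1632 in the wild type and 806 in the knockout sample and a log2 ratio of -1.02. The ventral and dorsal members named next, other than Eomes, Fezf2 and Tbr1, were chosen after their values were seen. Dlx5 and Dlx2, homeobox genes of the ganglionic eminences, had log2 ratios of -0.95 and -0.52. Gad2 and Gad1, which make GABA, stood at -0.63 and -0.53, and Slc32a1, the vesicular GABA transporter, at -0.55. Nkx2-1, which marks the medial ganglionic eminence, was at -0.36, and Sp8, at 0.33, was the 1 measured member higher. Lhx6, which acts downstream of Nkx2-1 in migrating interneurons, was above the floor in the wild type alone and was at least 3.63-fold lower in the knockout sample. Gsx1 and Olig2 were likewise above the floor in the wild type alone, and Otx2 in the knockout sample alone, by less than 2-fold each. The ventral median stood at percentile 0.01 of matched random lists.

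On the dorsal side, Eomes, a marker of intermediate progenitors of the cortex, was highest at 0.69, with a signal of 2855 in the wild type and 4581 in the knockout sample. Fezf2 and Tbr1, which specify deep-layer cortical neurons, were at 0.64 and 0.58. Neurog2 and Neurod2, proneural factors of the glutamatergic lineage, were at 0.52 and 0.58. Slc17a6, a vesicular glutamate transporter, was at 0.47 and Pax6 at 0.44. Emx1, Dmrt3, Wnt7b, Bcl11b and Neurod1 were lower, between -0.21 and -0.12. Otx1, a homeobox gene of the developing cortex that was on neither list, was above the floor in the knockout sample alone and was at least 3.27-fold higher there. The dorsal median lay above all 10000 random lists. It was 0.45 on MOE430A and 0.14 on MOE430B, where 8 members were measured and the percentile was 81.45; the ventral median was -0.42 on MOE430A, and fewer than 5 ventral genes were measured on MOE430B.

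**Figure D1:**
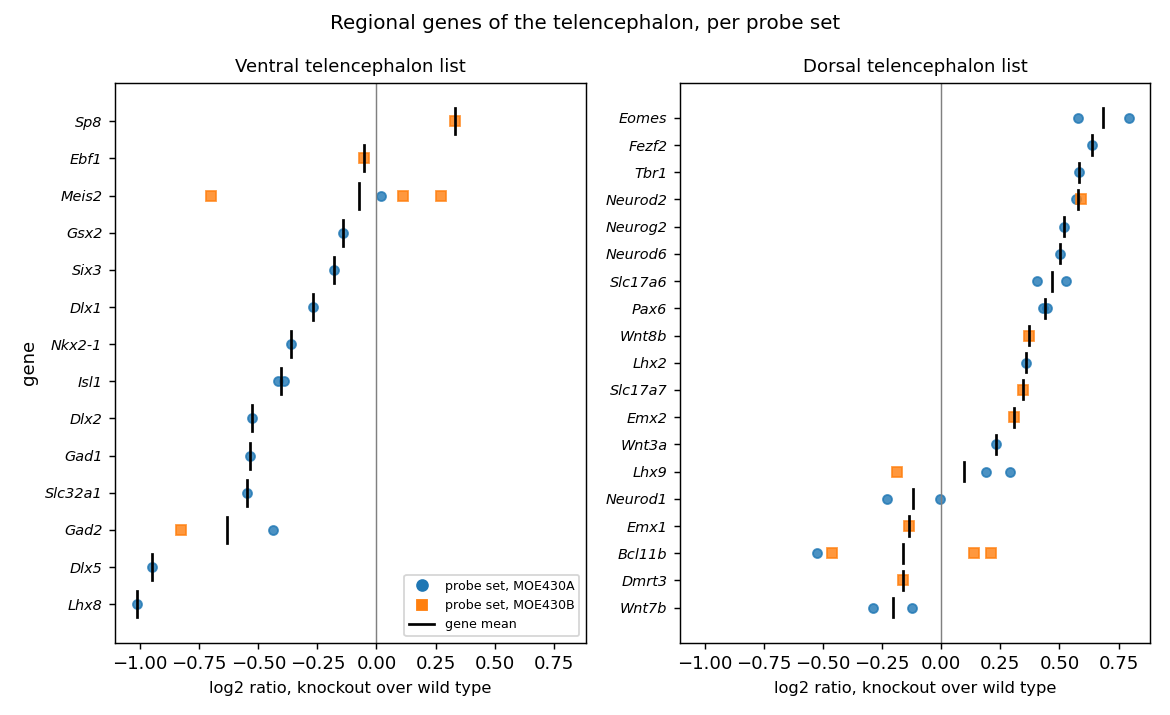
Log2 ratio of signal, knockout over wild type, for each measured probe set of the 14 ventral and 19 dorsal genes; circles are MOE430A and squares MOE430B probe sets, and the black bar is the gene's mean. Of the ventral genes 13 lie left of 0, from Lhx8 at -1.02 upwards, and 14 of the dorsal genes lie right of it, up to Eomes at 0.69.

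Among genes of neurons, Npy, a neuropeptide, was 1788 in the wild type and 955 in the knockout sample, a log2 ratio of -0.90. Nefl, a neurofilament subunit, was at -0.45 and Nsg2 at -0.41. Map2, Stmn3 and Elavl3, chosen after their values were seen, stood at -0.39, -0.39 and -0.38. Calb2 at 0.37, Syt4 at 0.25, Reln at 0.21 and Tubb3 at 0.03 were the 4 members on the other side. Sst, a neuropeptide of interneurons named after its values were seen, was above the floor in the wild type alone, at 2500, with a log2 bound of -1.76. The neuron median lay below all 10000 random lists, and it was -0.20 on MOE430A and -0.32 on MOE430B. Genes of neural stem and progenitor cells had a median of 0.09, at percentile 95.2, with 15 of 21 higher; it was 0.22, above all random lists, with the brightest probe set per gene and 0.02 at percentile 64.45 with no floor. Hmga2, a chromatin protein of fetal stem cells, was at 0.69 and Nfib at 0.35 with 7 probe sets from -0.52 to 1.36. Sox1 was at -0.61 from probe sets at -1.09 and -0.14. Sox2 and Nes, chosen after their values were seen, stood at 0.04 and -0.04.

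Genes of mitosis and the G2 phase were slightly higher in the knockout sample, with a median of 0.14 at percentile 99.9 and 31 of 39 measured genes higher. Kif20b and Ccnb2 were at 0.75 and 0.44, and Ckap2, a spindle protein, was at -0.85. The value of Kif20b rested on 1 probe set, with 3 others below the floor in 1 or both samples. The mitosis median was 0.14 on MOE430A and 0.06 on MOE430B, where it stood at percentile 67.6 over 10 genes, and it was 0.07 at percentile 97.45, just inside the random range, with a pseudocount in place of the floor. Genes of S phase and replication had a median of 0.06 at percentile 91.5, with 25 of 36 higher. Rfc5, a subunit of the clamp loader, was at 0.75, Mcm10 at -0.60 and Tk1 at -0.37. Cyclins, kinases and inhibitors of the G1 phase had a median of 0.02, with Ccnd2 at 0.49, Ccnd3 at 0.48 from probe sets at -0.10 and 1.06, and Cdkn1a at -0.43.

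Gas1 was the 1 gene higher by at least 2-fold on every measured probe set among genes with more than 1. Its probe sets read 3258 and 2755 in the wild type and 8726 and 6011 in the knockout sample, and a further probe set was below the floor in both. In the Sonic hedgehog list, 10 of 13 measured genes were higher and the median stood at percentile 99.3. Gli2, the main transcriptional activator of the pathway, was at 0.59 and Cdon, another co-receptor, at 0.43, while Shh was at -0.34. Among target genes of the pathway, Ptch1 was at -0.04, with probe sets at -0.34 and 0.25, and Gli1 and Hhip were below the floor. Foxf1 and Sfrp1, also on the list, were at 0.28 and 0.36. The 5 probe sets of Sfrp1 lay between -0.22 and 0.73. These members other than Gas1 were chosen after their values were seen. The median was 0.32 on MOE430A and 0.17 at percentile 90.35 on MOE430B, and 0.08 at percentile 89.2 with a higher floor, set at the 70th percentile of signals.

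Of 25 lists with enough measured genes, 9 stood outside the central 95% of random lists, where lists of unrelated genes would give 1.25. Genes of a list can vary together between cultures, so these 9 lists are not shown to exceed chance. Besides those above, ribosomal protein genes had a median of 0.15 at percentile 99.97 with 27 of 30 higher, and Rps27 was at 1.14; without the probe sets that can match several transcripts (_x_at, _s_at and _a_at) 11 genes were left, at percentile 92.525, inside the random range. Genes of hypoxia and glycolysis had a median of 0.15 at percentile 98.9, with Vegfa at 0.44 and Pgam1 at 0.37. Egln1 had a mean of 0.61 from 2 probe sets that disagreed, at -0.17 and 1.40. That median was 0.16 on MOE430A and -0.06 on MOE430B, it was -0.03 without the same probe sets, and it lay inside the random range in 6 of 11 alternatives, among them the floor at the 30th percentile of signals, at percentile 81.15, and lowess, at percentile 96.7. Genes of the interferon response had a median of -0.36 at percentile 0.84 over 6 measured genes, with Irf1 at -0.69, H2-K1 at -0.52 and Irf7 at -0.49; with the floor at the 30th percentile of signals, 12 genes were measured and the median was -0.03, inside the random range, as it was with no floor and with a pseudocount. Genes of red blood cells had a median of -0.28 at percentile 1.14 over 7 measured genes, with the embryonic globins Hbb-bh1 at -0.88, Hba-x at -0.51 and Hbb-y at -0.33; without the same probe sets 5 genes were left, with a median of -0.16 at percentile 16.1, inside the random range.

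The other lists lay inside the central 95% of random lists. The Notch pathway had a median of -0.06, with Heyl at 0.56 and Jag1 at -0.50. Its target Hes5 was at -0.86 from probe sets at -1.48 and -0.24. The Wnt pathway had a median of 0.06, with Lef1 at 0.84, Tcf7l2 at 0.59 and Znrf3 at 0.45. FGF and EGF receptor signalling had a median of -0.08, with Fgf15 at 0.59, Spry4 at 0.41 and Spred1 at 0.40. The 3 probe sets of Spred1 lay between 0.01 and 0.96. BMP and TGF-beta signalling had a median of 0.04, with Chrd at -0.70 and Id3 at -0.65. Bmpr2 was at -0.78 from probe sets at -1.61 and 0.05. Genes of the p53 response and apoptosis had a median of 0.08, with Bad at 0.49 and Bcl2l11 at 0.33. Bcl2l1 was at -0.56 from 3 probe sets between -1.10 and -0.24. Cholesterol biosynthesis genes had a median of 0.06, with Nsdhl at -0.43 and Dhcr7 at -0.42. Sc5d was at 0.36 from probe sets at -0.04 and 0.77. The median was 0.11 for immediate early and heat shock genes, with Nr4a1 at 0.55, Dusp1 at -0.40 and Asns at 0.30. Astrocyte genes had a median of 0.03 with Id3 at -0.65, Clu at 0.42 and Aqp4 at -0.30, and oligodendrocyte lineage genes one of -0.23 with Sox10 at -0.66, Cnp at -0.43, Mbp at -0.30 and all 6 measured genes lower. Endothelial genes had a median of -0.20 with Egfl7 at -0.39, Eng at -0.39 and Kdr at 0.38; Flt1, named after its values were seen, was above the floor in the knockout sample alone on 1 of its 4 probe sets, with a log2 bound of 1.24. Mesenchymal, meningeal and pericyte genes had a median of 0.11 with Fn1 at 0.38, Rgs5 at 0.29 and Acta2 at 0.29. Genes of extracellular matrix and adhesion had one of -0.01 with Itga5 at -0.71, Sdc1 at 0.51 and Ncam1 at -0.31. Fewer than 5 genes were measured for Hox genes, where Hoxa9 was at 0.38, Hoxc6 at -0.37 and Hoxa3 at -0.14, for microglia, where Laptm5 was at -0.63, Cd14 at 0.58 and Csf1r at -0.25, and for choroid plexus, where Kcnj13 was at 0.36 and Clic6 at 0.00.

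**Figure D2:**
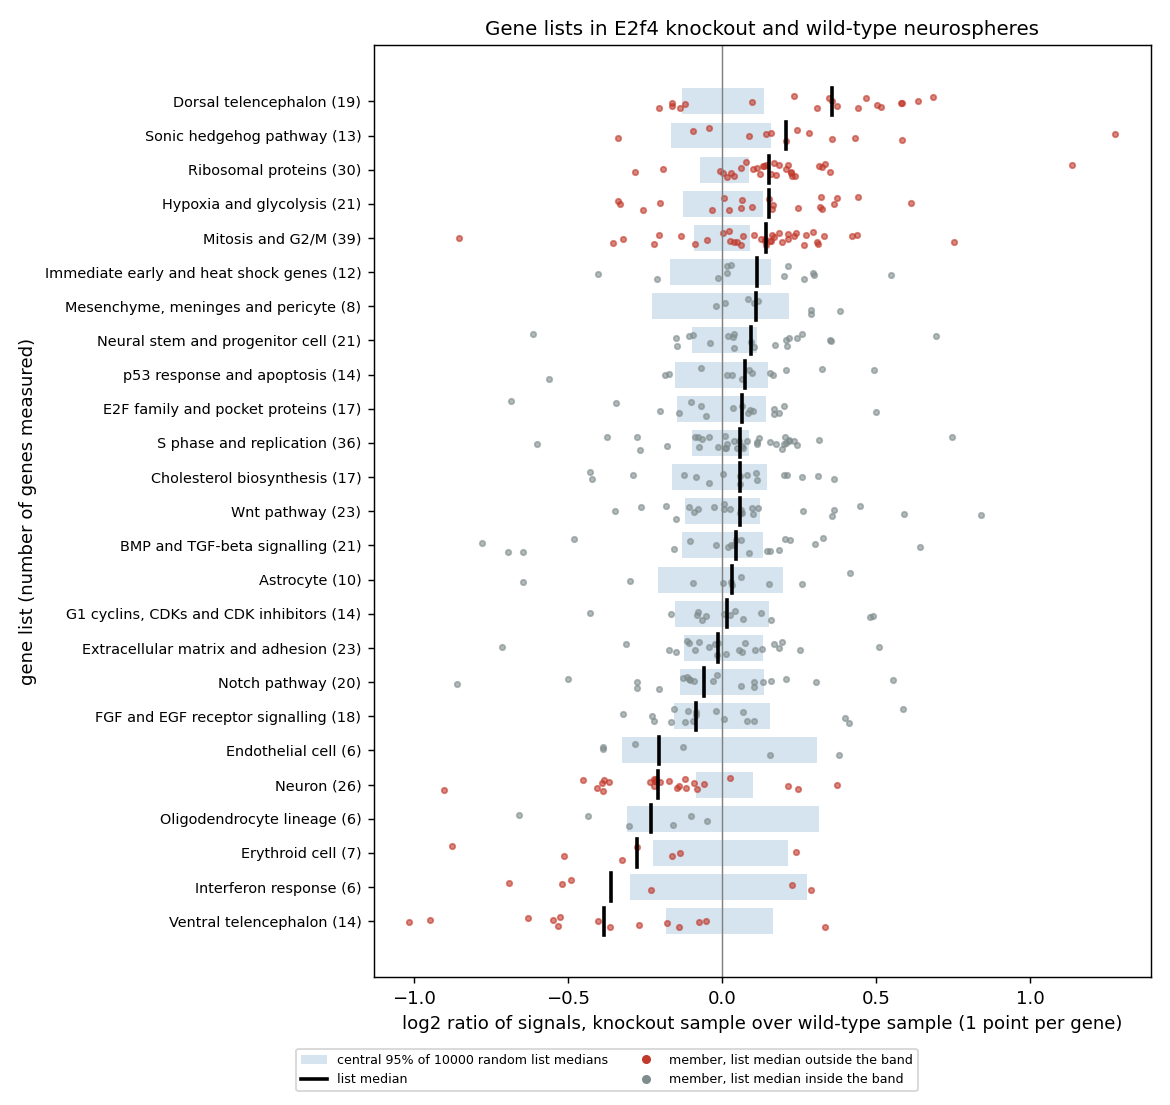
Log2 ratio of signal, knockout over wild type, for the measured genes (points) of each of 25 gene lists, with the list median (black bar) and the central 95% of medians of 10000 matched random lists (blue band); the number of genes measured follows each name. Medians outside the band (red points) run from -0.38 for the ventral telencephalon to 0.36 for the dorsal telencephalon.

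Across single genes, 54 were at least 2-fold higher and 49 at least 2-fold lower in the knockout sample, together 1.01% of 10174 measured genes. In the simulated arrays, 67 of 10016 unchanged genes passed the same size rule. A spread of that size alone can therefore pass many genes. It was set from the observed ratios, which include any real differences between the samples. How many of the 103 genes arise from error between arrays cannot be told. Xist, the non-coding RNA that silences one X chromosome in female cells, stood farthest from 0 at 7.60-fold lower, with signals of 8980 in the wild type and 1178 in the knockout sample. A further probe set was above the floor in the wild type alone, at 1817, and was at least 2.47-fold lower, and the remaining one was below the floor in both samples. Rusc2 was the 1 gene lower by at least 2-fold on every measured probe set among genes with more than 1, at 2.10-fold. The genes measured by 1 probe set that followed Xist were Depp1 at 4.40-fold lower, Pou5f2 at 3.11-fold, Fam209 at 2.82-fold, Shank1, a postsynaptic scaffold, at 2.67-fold, Spon2 at 2.56-fold, Fam131c at 2.51-fold and Wipf3 at 2.49-fold. On the higher side stood Bvht, U2af2, Ap1s1, H60c, Spats2, Prss51, Reep4 and Abcb8, with log2 ratios from 1.60 down to 1.24. Of genes above the floor in 1 sample only, Slco2b1 was at least 4.66-fold higher, Zbed5 4.00-fold, Gal3st2 3.73-fold and Rexo5 3.51-fold in the knockout sample, and St3gal6 was at least 6.20-fold lower, Dusp18 4.82-fold, Spata5 4.01-fold and Sema3f 3.90-fold.

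Most of these single-gene differences rested on 1 probe set, 51 of the 54 higher genes and 47 of the 49 lower ones. Where a probe set with a 2-fold difference had another measured probe set for its gene, the others lay on the same side in 66 of 134 cases and were also 2-fold in 4. Across 1342 genes with different probe sets on each design, the log2 ratios of the designs had a Pearson r of 0.05 and a Spearman rho of 0.05; this is across genes, which are not independent replicates. The pooled SD between probe sets of a gene was 0.33, and for 99 probe sets measured on both designs the SD of the difference was 0.31, with a Pearson r of 0.11 and a Spearman rho of 0.11 across probe sets. Counts of 2-fold genes were 11 higher and 9 lower among 6452 genes on MOE430A alone, and 54 and 53 among 5151 genes on MOE430B alone, of which 44 and 41 were among the genes counted over both designs.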

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

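The tests of the Xist probe sets and of Y-linked genes were chosen, and their bounds rewritten, after the values were seen; the list of escape genes was fixed before its values were seen. Probe sets without a single gene name entered no comparison, and 48 of them were at least 2-fold higher in the knockout sample than in the wild type, the largest 3.88-fold, while 45 were at least 2-fold lower; 91 of these 93 were on MOE430B.

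Xist was lower in the knockout sample. An error of a single Xist probe set is argued against, since 2 of 2 probe sets above the floor in a sample were lower by at least 2-fold. A smaller share of female cells in the knockout sample stays open: X-linked genes that escape inactivation had a median log2 ratio of -0.078, at percentile 22.5 of random lists, with Kdm5c at -0.69 and Jpx at 0.91. More male cells in the knockout sample also stay open, since 0 of 10 Y-linked probe sets reached the floor there and the 1 above it in the wild type, of Kdm5d, read 786 there and 697 in the knockout sample. The other 9 were below the floor in both samples, which gives no fold, and 7 of them read higher in the knockout sample and 2 lower. Among these, named after their values were seen, the probe sets of Eif2s3y read 111 and 131 in the wild type and 343 and 524 in the knockout sample, and another of Kdm5d read 466 and 690. A candidate explanation is that the embryos behind the samples differed in sex, and with 1 sample each this and an effect of genotype on Xist cannot be told apart.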

How the results depend on the processing

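The log2 ratio of E2f4 stayed between -0.25 and -0.17, with no value from MOE430B alone, where no probe set was named E2f4. The ventral, dorsal, neuron, mitosis, Sonic hedgehog, ribosomal, interferon and erythroid medians kept their sign under all alternatives listed with the processing that gave a value; the cause of the movements below was not tested unless stated. Counts of genes at least 2-fold higher and lower were 215 and 246 with a floor at the 30th percentile, 17 and 16 at the 70th, 1635 and 1547 with no floor, which adds dim probe sets, 11 and 9 on 430A only and 54 and 53 on 430B only. With a pseudocount the counts were 49 and 46, of which 5 and 3 genes were shared with the main 54 and 49. With the floor at the 30th percentile the Sonic hedgehog median was 0.30, hypoxia and glycolysis 0.063 and interferon -0.026; at the 70th, Sonic hedgehog was 0.083 and ventral -0.27. With no floor, Sonic hedgehog was 0.37 and interferon -0.00028. With a pseudocount, which shrinks ratios by construction, mitosis was 0.071 at percentile 97.45, just inside the random range, ventral -0.25, dorsal 0.27, neuron -0.15 and interferon -0.0047. Hypoxia and glycolysis lay inside the random range in 6 of 11 alternatives: the floor at the 30th percentile, quantile normalization, lowess, the brightest probe set, without _x_at, _s_at and _a_at probe sets, and 430B only. The ribosomal median was 0.094 with quantile normalization and 0.11 with lowess. Without _x_at, _s_at and _a_at probe sets, hypoxia and glycolysis reversed to -0.034 and the erythroid median was -0.16 at percentile 16.1, and the ribosomal list stood at percentile 92.525, both inside the random range. The stem cell median, inside the random range, was 0.22 and above it with the brightest probe set. On 430A only, Sonic hedgehog was 0.32 and dorsal 0.45. On 430B only, mitosis was 0.055, dorsal 0.14 and neuron -0.32, and hypoxia and glycolysis reversed to -0.056. Without GABAergic and Lhx6 or Lhx8 genes, a choice made after seeing the data, the ventral median was -0.22 at percentile 2.05. The Sonic hedgehog median of 0.18 without Gas1 and the dorsal median of 0.31 without neuronal members were such choices too. Of 1006 values of 107 named genes, 897 moved by less than the SD between probe sets and 109 by more. Many of these genes had 1 measured probe set, for which several alternatives return nearly the same value by construction. The count is therefore no measure of robustness. No paired analysis was possible because there was 1 sample per genotype. Leaving out members that sit in another list, also chosen after seeing the data, moved 5 lists, each by less than the SD of random lists. Signal over background limited the interferon list, which rested on 6 of 24 genes.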

Other observations

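A second pair of regional lists, written after the first pair had been seen and before their own values were, extended the regional comparison. The second ventral list had a median log2 ratio of -0.18 at percentile 0.91, with 10 of 14 measured genes lower. Dlx6os1, a non-coding RNA of the Dlx5 and Dlx6 locus, was at -0.85, Ackr3, a chemokine receptor of migrating interneurons, at -0.74, Zeb2 at -0.46 and Maf at -0.41. The second dorsal list had a median of 0.13 at percentile 94.985, with 11 of 15 measured genes higher. Dmrta2, a cortical patterning factor, was at 0.91, Cntn2 at 0.70, Mdga1 at 0.59 and Nhlh2 at -0.58. These genes were chosen after their values were seen.

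For the lower ventral and higher dorsal lists, the tests of the neuron share and of the founding region were chosen after the result was seen. A signal-dependent trend between the arrays is argued against. The dorsal minus ventral difference of medians was 0.74, and it was 0.73 with quantile normalization and with lowess. A constant scaling factor shifts both lists nearly alike, so the comparison with the deposited scaling could not decide anything. A lower share of neurons would by itself lower neuronal genes. The neuronal members of the dorsal list had instead a median of 0.49, with 6 of 8 higher. They belong to a list already seen to be higher. This outcome was therefore largely fixed in advance and decides nothing about the share of neurons. The lower ventral list was not covered by this test. Its median went from -0.38 to -0.22 without GABAergic and Lhx6 or Lhx8 genes, so a lower share of neurons stays open there too. A shift of regional identity beyond the fixed lists stays open, with a difference of 0.31 between the second lists of which the dorsal one lay within the range of random lists. With 1 RNA sample per genotype, the region that founded the cultures and an effect of E2f4 cannot be told apart.

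Embryonic globin signals were far above the floor in both samples, and the test of them was chosen after the result was seen. Hbb-y, which primitive red blood cells make, read 76647 in the wild type and 61020 in the knockout sample, Hba-x 27119 and 18976, and Hbb-bh1 5918 and 3214. Red blood cells in the neurosphere samples may be the source but stay open, since 3 of 6 other erythroid genes (Klf1, Epor and Tfrc) were above the floor in both samples, and Alas2, Slc4a1 and Gata1 were not. Epor and Tfrc are also expressed outside the erythroid lineage, the labels name no sort, and globin transcription in the neural cells themselves was not tested.

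A pair of hypotheses on the genome was fixed before its values were seen. An effect of the targeted locus on its neighbours stays open, as the 20 measured genes nearest to E2f4 on chromosome 8 had a median log2 ratio of -0.12, at percentile 7.08 of random lists; the margin at the edge of the random range that keeps it open was set after the value was seen. Gain or loss in most cells of a whole chromosome other than X and Y is argued against. The chromosome median farthest from 0 was -0.029, that of chromosome 5. It stood at percentile 1.4 of random lists but within the bound of 0.1 set beforehand. Chromosome Y had too few measured genes for a median, and a silenced X adds little signal. The test therefore cannot decide on Y or on loss of a silenced X. A gain or loss in part of the cells could also stay within the bound.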
